A study of Mus musculus with 12 samples.

How the data were processed

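RNA was measured in mouse oligodendrocyte progenitor cells (OPCs) transfected with a biotin-tagged control mimic or a biotin-tagged miR-27a mimic. A mimic is a synthetic double-stranded RNA that acts as a mature microRNA, and the biotin tag allows RNA bound to it to be captured on streptavidin. For each mimic, whole-cell RNA and RNA from the pulldown were sequenced, which gave 4 groups of 3 libraries. Groups and replicate numbers were taken from the sample titles. The sources used here do not state whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The sequence of the control mimic is not given in the sources used here.

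Per the series' design text, libraries were made with the TruSeq Stranded Total RNA kit with Ribo-Zero Globin depletion and sequenced as paired ends on a HiSeq instrument. Reads were trimmed and filtered with skewer, aligned with HISAT2 to the mouse genome GRCm38, sorted with SAMtools, counted per gene with featureCounts of the Subread package, and normalised by the authors in R with edgeR, per the same text. Tool versions are not given in the sources used here. The submitters' processing notes also name the build mm8, without a role. This library type keeps total RNA after ribosomal depletion and does not capture mature microRNAs of about the length of miR-27a.

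The authors deposited log2 CPM (CPM, read counts scaled to the library's size) for 20540 genes. Every library had the same lowest value, -6.27, which is the value of 0 reads with a prior of 0.25 reads. After taking 2 to the power of each value and subtracting that of 0 reads, 100% of the values in each library were whole multiples of 1 step, within a tolerance of 0.01 reads, so that CPM and whole reads were recovered. The libraries held 15548418 to 24972188 assigned reads, and the authors' library sizes implied normalisation factors from 0.961 to 1.055. A gene with 0 reads in a library had at most 0.116 to 0.2 CPM there, the CPM of 3 reads, which covers counting error only. Any read counts taken up by genes missing from the deposited table are not included in these totals.

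Tests were run with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with an empirical Bayes trend over mean expression, two-sided, and with Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. Genes with at least 1 CPM in at least 3 libraries of the fit were tested. Changes are therefore on the log2(CPM + 1) scale, which understates the change of low genes, and each is given with its standard error. For the mimics compared within whole-cell or pulldown RNA, this is over 3 against 3 libraries. For contrasts from the fit of all 12 libraries, the spread is pooled over the 4 groups. It is then not the spread of the groups compared alone. The comparisons were miR-27a against control mimic in whole-cell RNA (6 libraries), the same in pulldown RNA (6 libraries), and, from a fit of all 12 libraries, pulldown against whole-cell RNA under each mimic and the difference of these contrasts between mimics, called pulldown enrichment here. The planned count tests were not run, and limma voom on the recovered reads was added as an alternative. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.

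Before the data were examined, 25 gene lists were fixed, along with the tests, the alternatives and the rule for naming genes. Of the lists, 23 had at least 5 tested members. The mitochondrially encoded mRNAs and the genes of the miR-27 clusters had fewer. The 23 lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the lists of a comparison. Named genes were the 6 largest rises and the 6 largest falls among genes past the threshold with a group mean of at least 5 CPM, no overlap between replicate values and no provisional symbol (3 of each for pulldown against whole-cell RNA). Also named were up to 4 members of each list described with the smallest p, and Pdgfra, Olig2, Mbp, Runx1, Apc, Gsk3b, Ctnnb1 and Mir27a. Lists of smooth-muscle contractile genes, NRF2 target genes, replication-dependent histone genes, Y-linked genes and the X-linked homologs of the latter were added after the data were seen, and only their counts, medians and members are given.

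For seed sites, the longest annotated 3′ UTR of each gene was taken from GENCODE M21 (GRCm38). Of the 20540 genes, 19717 matched an annotated gene and 17016 had a 3′ UTR. Sites of miR-27a-3p, UUCACAGUGGCUAAGUUCCGC, were the 8mer ACTGTGAA, found in 1042 genes, and the 7mers ACTGTGA and CTGTGAA. An 8mer or 7mer was found in 4710 genes. For each 7mer found in at least 50 tested genes, the log2 change was regressed on its presence with 3′ UTR length, AT content and mean expression accounted for, and the seed 7mer was ranked by its t (the coefficient over its standard error) among 200 control 7mers of the same base composition. Genes without an annotated 3′ UTR counted as not searched. Standard errors and t of 7mers are over genes, which are not independent replicates, and do not measure the spread between libraries.

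The procedure was tested on simulated data with 50 genes changed at each fold. Genes were drawn independently from their real means, with a spread smoothed over mean expression and pooled over all groups. A larger spread of pulldown replicates was therefore not simulated, and the shares below for comparisons that use them may be too high. In whole-cell RNA, 62% of 1.25-fold changes, 86% of 1.5-fold changes and 96% of 2-fold changes were recovered, with 6 calls among unchanged genes. In pulldown RNA these shares were 60%, 96% and 100%, with 9 such calls. For the pulldown enrichment they were 24%, 84% and 96%, with 7 such calls. For pulldown against whole-cell RNA they were 56%, 88% and 98% under control mimic, with 11 such calls, and 44%, 92% and 98% under miR-27a, with 2 such calls.

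Replicates were compared before they were averaged. Pearson correlations of log2(CPM + 1) across genes were 0.989 to 0.997 within groups, and every pair of replicates differed by more than sampling noise. The chi-square per gene was 1.82 to 4.46 in whole-cell RNA and 4.24 to 28.06 in pulldown RNA. Replicate numbers were checked for pairing by the correlation of deviations from the group means across genes. In pulldown RNA, control and miR-27a libraries with the same number correlated at 0.141, 0.286 and 0.107, all above the bound of 0.1 set beforehand, so that the numbers were taken to pair these libraries. In whole-cell RNA the correlations were 0.002, -0.036 and -0.032. The pairing in pulldown RNA is inferred from these low correlations over genes alone and may not be real. The replicate block is a term for the replicate number in the fit. The main tests, fixed beforehand, held no block, so the pulldown values given are from an unpaired fit unless the block is named. Other alternatives were pseudocounts of 0.25 and 5 CPM, no filter, a filter at 5 CPM, TMM and median-of-ratios scaling, library totals, array weights, the deposited log2 values, a fit of all 12 libraries together or of the compared libraries alone, and leaving out each library in turn.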

Results

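OPCs, the glial precursors that become myelinating oligodendrocytes, were isolated from brains of C57BL/6 mice at postnatal day 6 to 7 and transfected with biotin-tagged control or miR-27a mimic. Whole-cell RNA and pulldown RNA were sequenced in 3 libraries per mimic. Assigned reads per library were 15548418 to 17591426 in whole-cell RNA under control mimic and 17441375 to 19106007 under miR-27a. In pulldown RNA they were 16341932 to 24972188 under control mimic and 19995638 to 21899644 under miR-27a. The first principal component held 65.3% of the variance and separated pulldown from whole-cell libraries, and the second held 14.4% and separated the mimics. Pulldown miR-27a replicate 2 stood apart on the third component, which held 5.4%. Mature miR-27a is not measured by these libraries, and the Mir27a gene held 5 reads in all, spread over 4 of the 12 libraries.

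The first comparison asked how the RNA content of the cells differed under miR-27a mimic. Ccnb1, the cyclin that drives entry into mitosis, rose from 52.4 ± 1.7 to 164 ± 4.5 CPM (SD, n = 3 each), a log2 change of 1.62 ± 0.04 (SE, adjusted p = 1.48e-17, chromosome 13, 100778650 to 100786570, GRCm38). Tnc, which encodes the extracellular matrix protein tenascin C, rose from 218 ± 7.0 to 474 ± 5.1 CPM, and Ccne2, a cyclin of S-phase entry, rose by 0.96 ± 0.07 (adjusted p = 6.05e-10). Acta2, smooth-muscle actin, fell from 46.0 ± 5.1 to 15.5 ± 1.4 CPM (log2 change -1.51 ± 0.08, adjusted p = 3.05e-12). Slc7a11, the cystine transporter that feeds glutathione synthesis, fell from 165 ± 8.2 to 59.3 ± 3.0 CPM (log2 change -1.46 ± 0.05, adjusted p = 2.99e-16). Most cell cycle genes tested rose, and 14 of 25 published miR-27 targets fell.

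Of 13393 genes tested, 3335 changed, 1736 higher and 1599 lower (1654 and 1689 with median-of-ratios scaling), with a median absolute log2 change of 0.27. At least 2-fold changes were 4 rises and 16 falls. The other leading rises were Hist1h2ao, a replication-dependent histone, Thsd4 and Sae1, which encodes part of the SUMO-activating enzyme, at log2 changes of 1.54 ± 0.20, 1.13 ± 0.07 and 0.95 ± 0.04. Hist1h2ao belongs to a family of similar histone genes, and reads shared between them were not measured. The other leading falls were Plau, the urokinase plasminogen activator, at -1.41 ± 0.09, and a group of contractile genes, Myl9 at -1.40 ± 0.05, Cnn1 at -1.40 ± 0.14 and Tagln at -1.32 ± 0.06. When all 12 libraries were fitted together, 1415 genes changed.

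Among the lists, 25 of 26 G2/M genes rose and none fell (25 adjusted over the list alone), with a median of 0.57 and adjusted p = 4.57e-33 by camera. Top2a, the topoisomerase of chromosome segregation, rose by 0.60 ± 0.03, Kif11, a spindle motor, by 0.69 ± 0.04 and the proliferation marker Mki67 by 0.57 ± 0.04. Of 25 G1/S genes, 18 rose and none fell (18 adjusted over the list alone), with a median of 0.25 and adjusted p = 1.03e-09, among them Uhrf1, a reader of hemimethylated DNA, at 0.89 ± 0.07 and the ribonucleotide reductase gene Rrm2 at 0.45 ± 0.05. Published miR-27 targets held 14 falls and 1 rise among 25 (15 and 1 adjusted over the list alone), with a median of -0.23 and adjusted p = 5.59e-09. They included the cholesterol exporter Abca1 at -0.56 ± 0.03, the cytochrome Cyp1b1 at -0.77 ± 0.06, the cyclin Ccng1 at -0.37 ± 0.03 and Nfe2l2, which encodes the antioxidant regulator NRF2, at -0.43 ± 0.05. These 3 lists each had an adjusted p = 0.0219 with an estimated correlation. Published targets were collected from general knowledge of miR-27 studies in other cells and not from these libraries.

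Interferon response genes fell in 12 of 20 cases with no rise (12 adjusted over the list alone), with a median of -0.24 and adjusted p = 4.71e-06. That list had an adjusted p = 0.362 with an estimated correlation and 0.0167, down, by fry. Rsad2, the antiviral protein viperin, fell by 1.16 ± 0.12 on the log2 scale, Ifit3 by 0.88 ± 0.12 and Gbp2 by 0.64 ± 0.09. Among astrocyte markers, 9 of 16 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of -0.19 and adjusted p = 8.12e-05. The adjusted p was 0.0575 with an estimated correlation and 0.000329, down, by fry. Aldh1l1, an astrocytic folate enzyme, went from 935 ± 41 to 602 ± 18 CPM, Ndrg2 from 574 ± 12 to 361 ± 15 CPM and the glutamate transporter Slc1a2 by a log2 change of -0.49 ± 0.03, all falls. Glul, glutamine synthetase, rose by 0.32 ± 0.03.

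The 3 lists of the oligodendrocyte lineage did not pass by camera. OPC markers held 10 rises and 3 falls among 24 (10 and 4 adjusted over the list alone, adjusted p = 0.0617 by camera and 0.0138, up, by fry), with Neu4, a sialidase, at 0.43 ± 0.04 and the lineage factors Olig1 at 0.41 ± 0.05 and Olig2 at 0.31 ± 0.04 among the rises. Myelin and mature oligodendrocyte genes held 4 rises and 7 falls among 25 (5 and 8 adjusted over the list alone, adjusted p = 0.31). The strongest member was Anln at 0.69 ± 0.05, which encodes the cytokinesis protein anillin and is also a G2/M list member. Committed and newly formed oligodendrocyte genes held 3 rises and 5 falls among 19 (3 and 6 adjusted over the list alone, adjusted p = 0.242). Pdgfra, the growth factor receptor that marks OPCs, went from 554 ± 5.3 to 502 ± 11 CPM (adjusted p = 0.00186), and Mbp, myelin basic protein, from 2820 ± 180 to 2500 ± 140 CPM (adjusted p = 0.00437). The Mbp call was lost without whole-cell miR-27a replicate 2 (adjusted p = 0.0507), and with all 12 libraries fitted together the adjusted p was 0.113 for Pdgfra and 0.141 for Mbp. Over all alternatives these values ran from 0.000337 to 0.113 for Pdgfra and from 7.63e-06 to 0.141 for Mbp.

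Genes of Wnt signalling went both ways. Wnt pathway components held 10 rises and 6 falls among 37 (12 and 6 adjusted over the list alone, adjusted p = 0.494) and Wnt target genes 2 rises and 2 falls among 10 (3 and 2 adjusted over the list alone, adjusted p = 0.819). Apc, the scaffold of the beta-catenin destruction complex, had a log2 change of -0.01 ± 0.04 (adjusted p = 0.869). Gsk3b, the kinase of that complex, was at 0.08 ± 0.06 (adjusted p = 0.328). Without whole-cell control replicate 1 Gsk3b had an adjusted p = 0.0462 in a range from 0.0462 to 0.775 over alternatives. Ctnnb1, beta-catenin, rose by 0.10 ± 0.03 (adjusted p = 0.0149). This call was lost without whole-cell control replicate 3 (adjusted p = 0.0847) and without whole-cell miR-27a replicate 3 (adjusted p = 0.0915), and the values ran from 0.0026 to 0.331 over alternatives. Runx1, a transcription factor and published miR-27 target, was at 0.549 ± 0.11 and 0.529 ± 0.11 CPM, below the level tested.

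The remaining lists did not pass by camera in whole-cell RNA. By fry, which tests whether a list's genes move on balance 1 way, genes of process growth (adjusted p = 0.0138, down) and cholesterol synthesis (adjusted p = 0.0114, up) passed. Markers of endothelial, mural and fibroblast cells held 3 rises and 2 falls among 8 (adjusted p = 0.875), of which Acta2 is 1. Microglial markers (1 rise and 1 fall of 12, adjusted p = 0.266), neuron markers (2 and 2 of 14, 0.716) and ependymal and choroid markers (1 and 0 of 5, 0.357) did not pass by camera. The same held for cell cycle inhibitors and p53 targets (9 and 4 of 19, 0.169), genes of process growth (3 and 6 of 17, 0.0524), and cholesterol synthesis (5 and 3 of 21, 0.654). It held for cytosolic ribosomal proteins (2 and 8 of 39, 0.266), immediate early genes (1 and 2 of 13, 0.422) and the integrated stress response (2 and 6 of 17, 0.357), and for miRNA pathway genes (4 and 0 of 22, 0.439), nuclear long non-coding RNAs (3 and 3 of 12, 0.654) and abundant small non-coding RNAs (2 and 0 of 10, 0.357). Among lists chosen after the data were seen, 48 of 51 replication-dependent histone genes rose (median 0.57), Hist1h2ao among them. Further, 7 of 12 smooth-muscle contractile genes fell (median -0.24), Acta2, Myl9, Cnn1 and Tagln among them. In addition, 9 of 19 NRF2 target genes fell with 1 rise (median -0.14), Slc7a11 among the falls. These lists hold genes that had been seen to change, so their counts are no independent test.

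**Figure D1:**
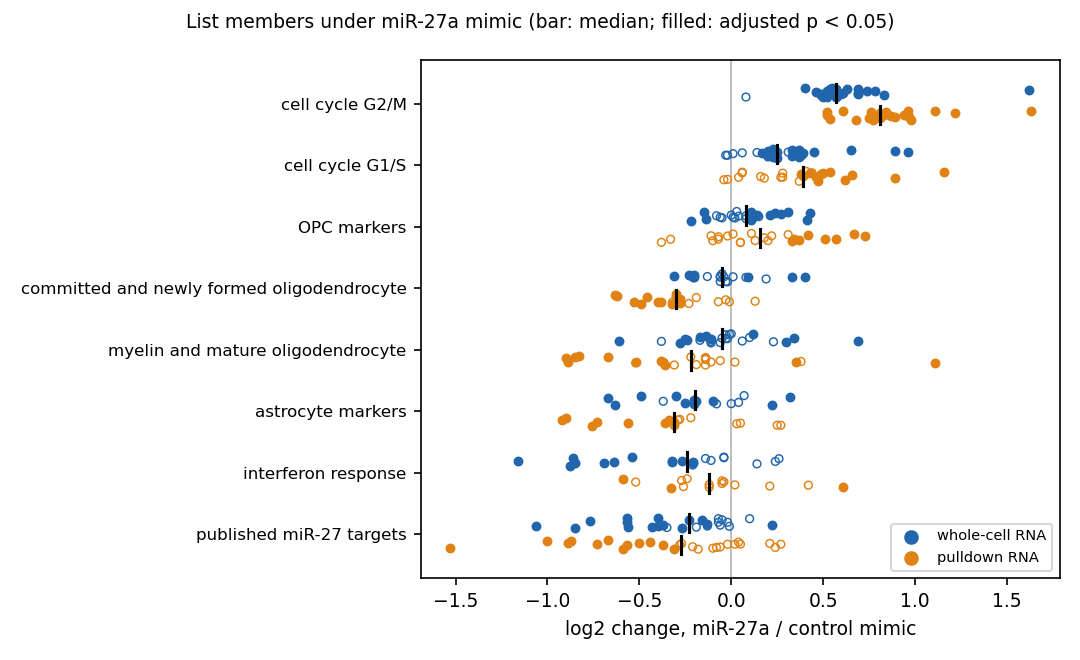
Log2 change under miR-27a mimic of each tested member of 8 gene lists in whole-cell RNA (blue) and pulldown RNA (orange), with filled points past an adjusted p of 0.05 and a bar at the list median. G2/M genes had medians of 0.57 in whole-cell RNA and 0.81 in pulldown RNA.

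The mimics were then compared in pulldown RNA, which mixes capture by the tagged mimic with the abundance of each RNA in the cells. Ccnb1 and Tnc rose here too, at 1.63 ± 0.10 (adjusted p = 8.66e-08) and 1.53 ± 0.09 (adjusted p = 7.07e-08), with Tnc going from 239 ± 6.1 to 695 ± 68 CPM. Other large rises were low genes, among them Fam19a4, a secreted chemokine-like protein, from 2.85 ± 0.51 to 13.1 ± 0.44 CPM (log2 change 1.88 ± 0.14, adjusted p = 1.08e-06). Mc4r, the melanocortin receptor, was at 1.74 ± 0.15, Ptgds, prostaglandin D synthase, at 1.70 ± 0.11 and Pnlip, a lipase, at 1.54 ± 0.17. Myl9 and Acta2 fell by 1.68 ± 0.18 and 1.65 ± 0.16 on the log2 scale, Scg2, the granin secretogranin II, from 137 ± 8.7 to 42.3 ± 1.6 CPM (log2 change -1.67 ± 0.09, adjusted p = 2.68e-08), and Plau by 1.59 ± 0.15. Adora2b, an adenosine receptor and published miR-27 target, fell by 1.53 ± 0.16 and Tmem51 by 1.37 ± 0.14.

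In all, 1781 of 13586 genes differed between the mimics in pulldown RNA, 822 higher and 959 lower (925 and 823 with library totals), 37 and 30 of them at least 2-fold. With the replicate block, which takes up the pairing inferred for these libraries, 2743 genes differed, all 1781 among them. With all 12 libraries in 1 fit 3051 differed. The count was 1002, 1180 and 969 without pulldown control replicates 1, 2 and 3, and 2691 and 1029 without pulldown miR-27a replicates 2 and 3, and it was 5102 with array weights.

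All 26 G2/M genes tested rose in pulldown RNA (26 adjusted over the list alone), with a median of 0.81 and adjusted p = 5.5e-32, and 12 of 25 G1/S genes rose with none falling (16 adjusted over the list alone, median 0.39, adjusted p = 9.7e-09). With an estimated correlation these lists had an adjusted p = 0.0804 and an adjusted p = 0.30, and by fry 0.000718 and 0.0387. Top2a went from 209 ± 17 to 412 ± 13 CPM and Anln from 22.2 ± 0.8 to 49.0 ± 1.8 CPM. Published miR-27 targets held 12 falls and no rise among 26 (14 and 1 adjusted over the list alone, median -0.27, adjusted p = 2.28e-06, adjusted p = 0.0861 with an estimated correlation and 0.000718 by fry), with Cyp1b1 at -0.89 ± 0.09 and Abca1 at -0.73 ± 0.08. Astrocyte markers held 9 falls and no rise among 16 (12 and 1 adjusted over the list alone, median -0.31, adjusted p = 4.54e-06, adjusted p = 0.411 with an estimated correlation and 0.0619 by fry), with Gfap, the astrocyte filament protein, from 877 ± 41 to 532 ± 75 CPM.

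In pulldown RNA lists of the oligodendrocyte lineage passed by camera at the preset correlation and not with an estimated one. They also passed by fry, which tests a list against no change and not against other genes. The adjusted p by fry was 0.0127 for committed oligodendrocyte genes, 0.0209 for myelin genes and 0.0166 for OPC markers. Committed and newly formed oligodendrocyte genes held 11 falls and no rise among 19 (14 and 0 adjusted over the list alone, median -0.30, adjusted p = 2.25e-07). Myelin genes held 9 falls and 2 rises among 23 (9 and 2 adjusted over the list alone, median -0.22, adjusted p = 1.31e-04). With an estimated correlation these had an adjusted p = 0.16 and an adjusted p = 0.30. Mbp fell from 796 ± 63 to 440 ± 8.9 CPM (log2 change -0.85 ± 0.08, adjusted p = 1.24e-05). Mag, a myelin-associated glycoprotein, fell from 414 ± 60 to 221 ± 7.6 CPM and the iron carrier Trf from 224 ± 21 to 126 ± 9.1 CPM, and the rises again included Anln. OPC markers held 8 rises and no fall among 24 (10 and 2 adjusted over the list alone, median 0.15, adjusted p = 6.34e-04, adjusted p = 0.16 with an estimated correlation), with the proteoglycans Cspg4 at 0.73 ± 0.12 and Vcan at 0.51 ± 0.10. Pdgfra was at 0.18 ± 0.09 (adjusted p = 0.208), with adjusted p from 0.0196 to 0.464 over alternatives and 0.0245 with all 12 libraries in 1 fit. Olig2 was at 0.20 ± 0.08 (adjusted p = 0.108), with an adjusted p = 0.0358 with the replicate block and 0.00875 without pulldown miR-27a replicate 2, in a range from 0.000458 to 0.359 over alternatives.

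Apc, Gsk3b, Ctnnb1 and Runx1 had log2 changes of 0.21 ± 0.11, 0.07 ± 0.09, 0.18 ± 0.09 and 0.05 ± 0.22 in pulldown RNA, with adjusted p = 0.231, 0.693, 0.214 and 0.91. Without pulldown miR-27a replicate 1 Apc had an adjusted p = 0.0137 (0.0128 to 0.532 over alternatives), and without pulldown miR-27a replicate 2 Ctnnb1 had an adjusted p = 0.038 (0.0152 to 0.45 over alternatives). Interferon response genes held 1 rise and 2 falls among 15 (adjusted p = 0.305). Abundant small non-coding RNAs had a median of -0.21 (adjusted p = 0.0697), which passed with the replicate block (adjusted p = 0.0429, adjusted p = 0.30 with an estimated correlation and no block). By fry that list had an adjusted p = 0.0166, down. No other list passed by camera in pulldown RNA, with adjusted p from 0.173 to 0.972. Of the lists chosen after the data were seen, histone genes held 32 rises among 51, contractile genes 7 falls among 12 and NRF2 target genes 5 falls among 18.

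Changes in pulldown RNA followed those in whole-cell RNA across genes. Over 13203 genes tested in both, which are not independent replicates, Pearson's r of the log2 changes was 0.639 and Spearman's rho 0.534, from comparisons that share no library. Of 3315 genes that changed in whole-cell RNA, 86.7% had the same sign in pulldown RNA, and the slope of the pulldown change on the whole-cell change was 0.903. Both comparisons called 550 genes higher, where 105.9 would be called if the lists were independent, and 594 lower, where 114.2 would be. Genes higher in pulldown RNA and lower in whole-cell RNA, as captured targets degraded in the cells would be, numbered 6, where 97.5 would be called if the lists were independent (Fisher's exact test across genes, two-sided, p = 1.54e-37). The opposite set, lower in pulldown RNA and higher in whole-cell RNA, numbered 12, where 124.1 would be called (p = 7.58e-43 by the same exact test), so both sets were short, as they are where the changes follow each other. The 6 genes were Akap12, Pcdh15, Srp54b, Net1, Ncald and Itga8, named for their small number after their values were seen, and of these Net1 and Ncald carried a miR-27a 7mer site and none an 8mer. The count of 6 became 2 and 3 without whole-cell miR-27a replicates 1 and 3, 3 without pulldown control replicate 1, 3 or pulldown miR-27a replicate 3, 16 without pulldown miR-27a replicate 1, and 11 with the replicate block.

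**Figure D2:**
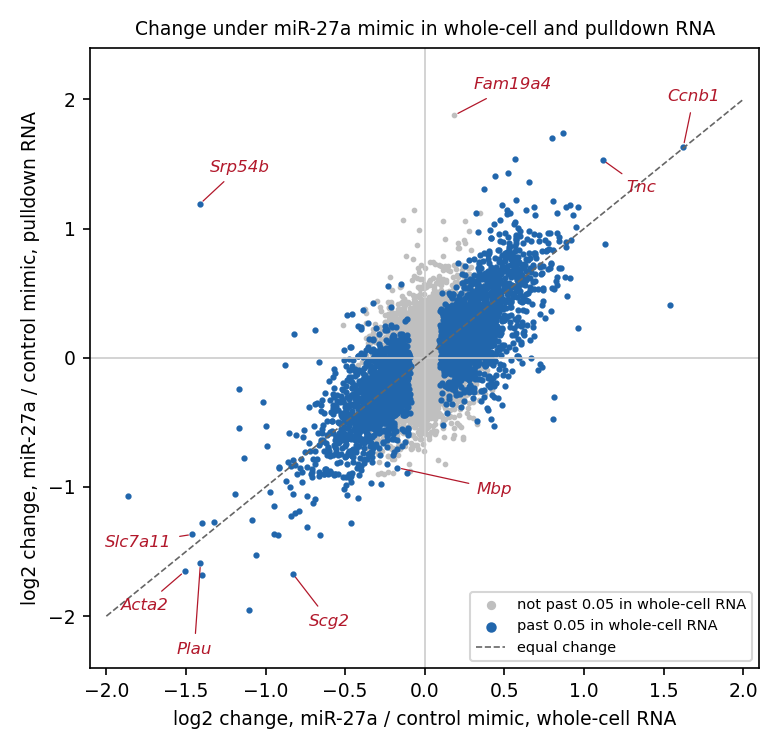
Log2 change under miR-27a mimic of each of 13203 genes in whole-cell RNA (horizontal) and pulldown RNA (vertical), with genes past an adjusted p of 0.05 in whole-cell RNA in blue and a dashed line of equal change. The points follow the line (slope 0.903 over the blue points), and Srp54b and Fam19a4 lie away from it.

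Pulldown enrichment is the pulldown-to-whole-cell difference under miR-27a minus that under control mimic. Whether pulldown and whole-cell libraries came from the same cultures stays open, given the sex-linked genes described below. Enrichment may therefore hold differences between cultures besides capture. Fam19a4 (1.69 ± 0.20, adjusted p = 0.000217) and Atp10b, a phospholipid flippase (1.20 ± 0.14, adjusted p = 0.000217), were more enriched under miR-27a. So were the potassium channel gene Kcna5 (1.21 ± 0.21, adjusted p = 0.0067), Capn6 (0.97 ± 0.10, adjusted p = 0.000217) and the ectonucleotidase Nt5e (0.95 ± 0.16, adjusted p = 0.00552). Scg2 (-0.85 ± 0.10, adjusted p = 0.000217), Nkx6-2, a homeobox gene of oligodendrocytes (-0.96 ± 0.14, adjusted p = 0.00249), and Mbp (-0.68 ± 0.10, adjusted p = 0.00249) were less enriched. So were the myelin genes Mag (-0.78 ± 0.11), Gal3st1 (-0.64 ± 0.10) and Trf (-0.59 ± 0.10). None of the 5 genes named as more enriched carried a miR-27a 8mer or 7mer site in its 3′ UTR. Srp54b had the largest value, 2.60 ± 0.49 (adjusted p = 0.0124), with an adjusted p = 0.057 without whole-cell miR-27a replicate 3 and a range from 0.000269 to 0.0985 over alternatives. The related genes Srp54a and Srp54c were at -0.30 ± 0.20 and 0.02 ± 0.13, and reads shared between these genes and Srp54b were not measured.

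In this comparison 149 of 13875 genes differed, 47 higher and 102 lower, and the split was 53 higher and 72 lower with median-of-ratios scaling. The count was 54 and 53 without whole-cell control replicates 1 and 3, 57, 66 and 43 without whole-cell miR-27a replicates 1, 2 and 3. It was 90 and 49 without pulldown control replicates 1 and 3, 359 and 473 without pulldown miR-27a replicates 1 and 2, 73 without a filter and 1735 with array weights. Pdgfra was at 0.32 ± 0.08 (adjusted p = 0.0511) and passed without pulldown miR-27a replicate 1 (adjusted p = 0.0325) and without replicate 2 (adjusted p = 0.00274), in a range from 0.000173 to 0.186 over alternatives. Olig2, Apc, Gsk3b, Ctnnb1 and Runx1 were at -0.11 ± 0.08, 0.22 ± 0.12, -0.01 ± 0.11, 0.08 ± 0.08 and 0.07 ± 0.26, with adjusted p = 0.625, 0.482, 0.975, 0.758 and 0.945.

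By list, 4 of 26 G2/M genes were more enriched and none less (6 and 0 adjusted over the list alone, median 0.25, adjusted p = 3.64e-09), with the chromatin protein gene Hmgb2 at 0.53 ± 0.09. Committed oligodendrocyte genes held 4 falls and no rise among 19 (10 and 0 adjusted over the list alone, median -0.26, adjusted p = 3.64e-09). Myelin genes held 5 falls and 1 rise among 25 (8 and 1 adjusted over the list alone, median -0.29, adjusted p = 3.76e-05). OPC markers held 1 rise, Pcdh15 at 0.72 ± 0.11, and no fall among 24 (7 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.00617). These 4 lists each had an adjusted p = 0.0768 with an estimated correlation, and 0.0176, 0.00758, 0.00758 and 0.0439 by fry. Astrocyte markers (median -0.22, adjusted p = 4.1e-04), interferon response genes (median 0.15, adjusted p = 5.56e-04), abundant small non-coding RNAs (median -0.27, adjusted p = 0.00614) and cytosolic ribosomal proteins (median 0.07, adjusted p = 0.0113) held 1, 1, 2 and 0 members past the threshold. These lists had adjusted p = 0.483, 0.32, 0.32 and 0.816 with an estimated correlation and 0.187, 0.152, 0.143 and 0.718 by fry. Of the 20 interferon response genes tested here, 15 passed the filter in the pulldown comparison. Since log2(CPM + 1) understates falls of low genes, their rise in enrichment may come from low values in pulldown RNA. Published miR-27 targets held 1 rise and no fall among 26 (1 and 1 adjusted over the list alone, median -0.06, adjusted p = 0.468). The other lists had adjusted p from 0.0596 to 0.939.

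Seed sites for miR-27a were then compared across genes. In whole-cell RNA, 32.3% of 841 genes with the 8mer ACTGTGAA in the 3′ UTR fell and 8.0% rose, against 9.1% and 14.5% of 8659 genes without an 8mer or 7mer. The median log2 difference from genes without a site was -0.045 for genes with any site (camera p = 0.000904, p = 0.0182 with an estimated correlation) and -0.117 for genes with the 8mer (p = 3.8e-11, 0.00235 with an estimated correlation). After matching on 3′ UTR length and expression it was -0.055 and -0.126. Among it and 200 control 7mers of the same base composition ACTGTGA had the lowest t, -15.11, with a change of -0.078 ± 0.005. It had the lowest t of all 16162 7mers tested, and CTGTGAA was next at -12.99. Acta2 carried 1 8mer in its 3′ UTR (chromosome 19, 34241631 to 34241638, GRCm38, minus strand), Slc7a11 1 at chromosome 3, 50371897 to 50371904 (minus strand), and Adora2b 3 at chromosome 11, 62265797 to 62265804, 62266031 to 62266038 and 62266041 to 62266048 (plus strand). Plau, Cyp1b1 and Nfe2l2 carried 7mers, while Myl9, Cnn1 and Tagln carried no site. Apc, Gsk3b and Olig2 also carried a site, and in whole-cell RNA Olig2 rose and Apc and Gsk3b did not pass the threshold. Pdgfra and Mbp carried a site and fell, and Runx1 carried one and was below the level tested.

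In pulldown RNA 17.7% of 857 genes with the 8mer were lower and 3.9% higher, against 5.8% and 6.5% of 8755 genes without a site. ACTGTGA again had the lowest t, -12.2, with a change of -0.081 ± 0.007 (camera p = 0.0438 for any site, p = 0.17 with an estimated correlation, and p = 3.84e-06 for the 8mer, 0.0531 with an estimated correlation). In pulldown enrichment the change of ACTGTGA was -0.003 ± 0.005, rank 154 by t from the most enriched. Of 872 genes with the 8mer 0.2% were more enriched and 0.6% less, against 0.4% and 0.8% of 8915 genes without a site. Against genes without a site, limma's camera gave p = 0.705 for those with any site and p = 0.9 for those with the 8mer (0.751 and 0.938 with an estimated correlation). Under control mimic ACTGTGA ranked 87 and under miR-27a mimic 114 by t from the most enriched for pulldown against whole-cell RNA.

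The 7mer with the highest t was GGTTGTG, at 12.82 in whole-cell RNA and 10.11 in pulldown RNA, with changes of 0.078 and 0.079. This sequence was singled out after its values were seen, and it is complementary to positions 2 to 8 of cel-miR-67-3p, UCACAACCUCCUAGAAAGAGUAGA, a worm miRNA widely used as a control mimic. Of 494 genes with GGTTGTGA in the 3′ UTR, 30.4% rose and 5.9% fell in whole-cell RNA, against 11.8% and 12.7% of 10061 genes without this site or its 7mers. Ccnb1 and Sae1 carried GGTTGTGA. Without genes that carry such a site or its 7mers, 22 of 23 G2/M genes rose (median 0.57) and 13 of 19 G1/S genes (median 0.23). Of OPC markers, 6 of 19 without such a site rose in whole-cell RNA (median 0.02, against 0.08 over all 24) and 5 of 19 in pulldown RNA (median 0.05, against 0.15).

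**Figure D3:**
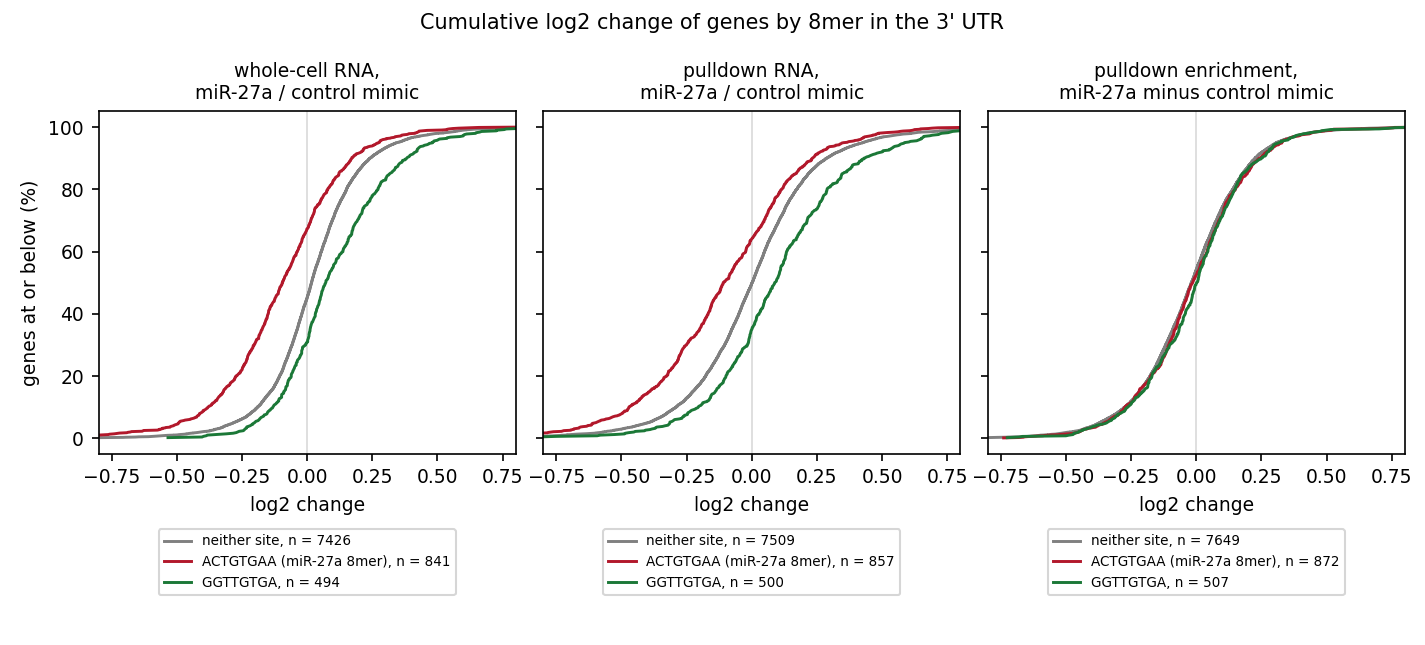
Cumulative share of genes (percent) at or below each log2 change in whole-cell RNA, pulldown RNA and pulldown enrichment, for genes with the miR-27a 8mer ACTGTGAA, with GGTTGTGA, or with neither kind of site. In the first panel 841 genes with ACTGTGAA lie to the left and 494 genes with GGTTGTGA to the right of the rest, and in the third panel the curves overlap.

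The last comparisons set pulldown against whole-cell RNA under each mimic. Differences here may likewise include differences between cultures, which the sex-linked genes below leave open. Under control mimic Dll3, a Notch ligand, rose from 12.6 ± 1.2 to 60.8 ± 3.4 CPM (log2 change 2.19 ± 0.09, adjusted p = 1.8e-12). Fn1, fibronectin, rose from 9.03 ± 0.43 to 39.8 ± 0.69 CPM and the collagen gene Col1a2 from 0.805 ± 0.23 to 6.68 ± 0.21 CPM. The interferon-induced genes Ifit1 and Usp18 were lower in pulldown RNA, with log2 changes of -2.37 ± 0.17 and -2.33 ± 0.15, and the myelin gene Mobp at -2.30 ± 0.13. Under miR-27a Fam19a4 (2.59 ± 0.14), Col1a2 (2.58 ± 0.15) and Atp10b (2.25 ± 0.10) led the rises, and Mobp (-2.60 ± 0.13), Mbp (-2.50 ± 0.07) and Ddc, a decarboxylase of monoamine synthesis (-2.36 ± 0.09), led the falls. Of 13875 genes, 8601 differed under control mimic, 4392 higher and 4209 lower. The balance was 5176 and 3401 with library totals as the scaling, and it turned to 4232 and 4348 with median-of-ratios scaling and to 3793 and 3973 with a filter of at least 5 CPM. Under miR-27a 8350 differed, 4064 higher and 4286 lower (5009 and 3312 with library totals). The log2 differences of the mimics correlated across genes at r = 0.899 and rho = 0.897, with no library shared.

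OPC markers were higher in pulldown RNA, with 18 rises and no fall among 24 under control mimic (18 and 0 adjusted over the list alone, median 0.75, adjusted p = 8.38e-07, adjusted p = 0.0128 with an estimated correlation). They held 20 rises and no fall under miR-27a (20 and 2 falls adjusted over the list alone, median 0.71, adjusted p = 1.49e-08, adjusted p = 0.00544 with an estimated correlation). Pdgfra was at 554 ± 5.3 CPM in whole-cell RNA and 1370 ± 19 CPM in pulldown RNA under control mimic. Markers of endothelial, mural and fibroblast cells held 9 rises and 2 falls among 12 under each mimic (medians 1.26 and 1.28, adjusted p = 0.000585 and 0.000418, adjusted p = 0.135 and 0.111 with an estimated correlation). Interferon response genes held 18 falls among 20 under control mimic and 17 with 1 rise under miR-27a, each the same adjusted over the list alone (medians -1.06 and -0.79, adjusted p = 8.38e-07 and 5.96e-05). Myelin genes held 15 falls and 5 rises, and 17 and 4, among 25 (16 and 5, and 17 and 4, adjusted over the list alone, medians -0.54 and -0.69, adjusted p = 0.00505 and 0.000266). With an estimated correlation the interferon list had adjusted p = 0.14 and 0.155 and the myelin list adjusted p = 0.184 and 0.111. G1/S genes held 19 falls among 25 under each mimic (20 adjusted over the list alone, medians -0.42 and -0.33, adjusted p = 3.82e-05 and 0.000273, adjusted p = 0.218 and 0.273 with an estimated correlation). Wnt pathway components held 26 rises and 6 falls, and 23 and 4, among 38 (26 and 6, and 24 and 4, adjusted over the list alone, medians 0.48 and 0.32, adjusted p = 0.000585 and 0.00111, adjusted p = 0.135 and 0.111 with an estimated correlation).

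Further lists passed by camera at the preset correlation and not with an estimated one, where their adjusted p ran from 0.111 to 0.659. By fry the lists of this and the preceding paragraph passed under both mimics, with adjusted p from 3.47e-09 to 0.0258. Cytosolic ribosomal proteins under miR-27a were the exception. Fry tests a list against no change and not against other genes, most of which differed here. Genes of process growth held 13 falls and 2 rises, and 13 and 3, among 17 (13 and 2, and 14 and 3, adjusted over the list alone, medians -0.55 and -0.55, adjusted p = 0.000585 and 0.000418). Neuron markers held 8 falls and 1 rise, and 9 and 2, among 14 (8 and 1, and 10 and 2, adjusted over the list alone, medians -0.42 and -0.41, adjusted p = 0.0178 and 0.00705). Cytosolic ribosomal proteins held 22 and 14 falls and no rise among 39 (17 and 10 adjusted over the list alone, medians -0.17 and -0.10, adjusted p = 0.00112 and 0.0271). Under miR-27a their median was 0.01 with library totals, and by fry the list had an adjusted p = 0.0937. Immediate early genes held 8 rises and no fall, and 7 and 1, among 14, the same adjusted over the list alone (medians 0.40 and 0.30, adjusted p = 0.0133 and 0.0174). Wnt target genes held 7 rises and 1 fall, and 8 and 1, among 12, the same adjusted over the list alone (medians 0.32 and 0.56, adjusted p = 0.0243 and 0.0101). Some lists passed under 1 mimic. G2/M genes held 17 falls and 3 rises among 26 under control mimic (17 and 3 adjusted over the list alone, median -0.38, adjusted p = 0.00112) and 10 and 4 under miR-27a (9 and 4 adjusted over the list alone, median -0.12, adjusted p = 0.248). Under control mimic miRNA pathway genes (median 0.29, adjusted p = 0.0435, 0.0761 under miR-27a) and the integrated stress response (median 0.32, adjusted p = 0.0433, 0.0536 under miR-27a) passed. Under miR-27a committed oligodendrocyte genes (median -0.36, adjusted p = 0.000544, 0.0805 under control mimic) and astrocyte markers (median -0.46, adjusted p = 0.0197, 0.134 under control mimic) passed. The differences between the mimics are those given for pulldown enrichment.

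Y-linked genes and Xist, the RNA that silences an X chromosome in female cells, differed between the fractions alongside these lists. Eif2s3y was at 149 ± 8.3 and 31.2 ± 1.7 CPM in whole-cell and pulldown RNA under control mimic (log2 change -2.22 ± 0.14, adjusted p = 2.61e-10) and Ddx3y at 129 ± 6.4 and 30.6 ± 2.1 CPM (log2 change -2.04 ± 0.12, adjusted p = 1.53e-10). Kdm5d and Uty were at -1.48 ± 0.09 and -1.52 ± 0.13, and under miR-27a Ddx3y, Kdm5d and Uty were at -2.04, -1.54 and -1.40. Xist was at 113 ± 4.9 CPM in whole-cell RNA and 339 ± 22 CPM in pulldown RNA under control mimic (log2 change 1.58 ± 0.08) and differed by 1.77 ± 0.08 under miR-27a. The X-linked homologs Eif2s3x, Ddx3x, Kdm5c and Kdm6a lay between -0.60 and 0.27. These genes were chosen after the data were seen. Whether the fractions came from cultures with different shares of male and female cells is taken up below.

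**Figure D4:**
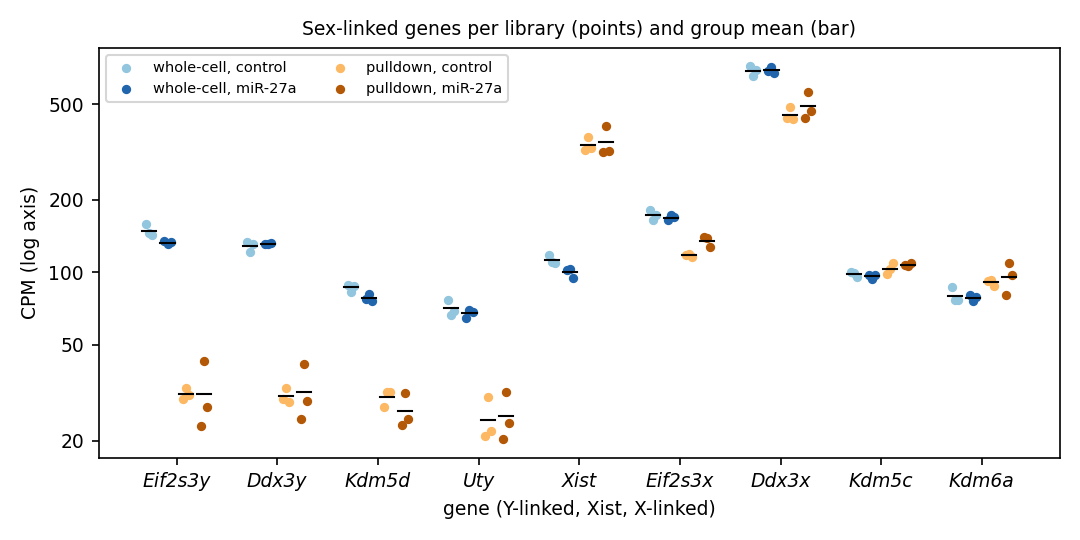
CPM on a log axis of 4 Y-linked genes, Xist and the 4 X-linked homologs in each of the 12 libraries (points) with group means (bars). Xist was at 113 CPM in whole-cell RNA and 339 CPM in pulldown RNA under control mimic, and the Y-linked genes lay below their whole-cell level in every pulldown library.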

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

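The tests of the Y-linked genes and Xist, of the slope between whole-cell and pulldown changes and of GGTTGTG sites were chosen after the results were seen. The rank of the miR-27a seed 7mer and the counts over other splits of the libraries were planned.

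The effect of the mimic differed between pulldown and whole-cell RNA, by a test of the difference itself, for 149 genes. The named ones had log2 differences of 2.60 for Srp54b, 1.69 for Fam19a4, 1.21 for Kcna5, 1.20 for Atp10b, 0.97 for Capn6 and 0.95 for Nt5e. Those of the falls were -0.96 for Nkx6-2, -0.85 for Gng4, -0.85 for Scg2, -0.80 for Sema4a, -0.80 for Snora78, -0.79 for Adc and -0.68 for Mbp. By list the medians were 0.25 for G2/M genes, 0.15 for interferon response genes, 0.07 for cytosolic ribosomal proteins and 0.06 for OPC markers, and -0.29 for myelin genes, -0.27 for abundant small non-coding RNAs, -0.26 for committed oligodendrocyte genes and -0.22 for astrocyte markers. None of these 8 lists passed with an estimated correlation, where adjusted p ran from 0.0768 to 0.816. By fry the G2/M, committed oligodendrocyte, myelin and OPC lists passed (adjusted p = 0.0176, 0.00758, 0.00758 and 0.0439) and the other lists did not. Single libraries were not tested as outliers in groups of 3.

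Some of these calls were lost when 1 library was left out, for Adc, Sema4a and Snora78 with any of several libraries. Srp54b had an adjusted p = 0.057 without whole-cell miR-27a replicate 3 (0.000269 to 0.0985 over alternatives). Adc had 0.0547 and 0.0506 without whole-cell control replicates 1 and 3, 0.0605 without whole-cell miR-27a replicate 3 and 0.063 without pulldown control replicate 3 (0.000187 to 0.063). Sema4a had 0.0629 and 0.0601 without whole-cell control replicates 1 and 2, 0.0561, 0.0539 and 0.0908 without whole-cell miR-27a replicates 1, 2 and 3, and 0.0821 without pulldown control replicate 3 (0.00139 to 0.0908). Snora78 had 0.0944 without whole-cell control replicate 1 or 3, 0.0994, 0.0824 and 0.0511 without whole-cell miR-27a replicates 1, 2 and 3, 0.0806 and 0.0718 without pulldown control replicates 1 and 3, and 0.0628 without pulldown miR-27a replicate 3 (0.000254 to 0.0994).

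Of 100 splits drawn from the 200 possible for this comparison, 8 gave at least 149 genes, the real one included, and the highest other gave 1101, so chance cannot be excluded by this count. The 7 others were among 11 splits that kept the real mimic labels in pulldown RNA and mixed them in whole-cell RNA, so that the mimic effect on pulldown RNA itself entered the difference. The 6 splits that kept the labels in whole-cell RNA gave 0, as did the splits that kept them in neither. For the other comparisons, 10 splits are too few for a share under 0.05, and the real split was the 1 with the highest count in each. The counts were 3335 genes against 0 in the highest other split for whole-cell RNA, 1781 against 0 for pulldown RNA, 8601 against 0 for pulldown against whole-cell RNA under control mimic and 8350 against 0 under miR-27a. In pulldown RNA, 4 splits part all 3 pairs of replicate numbers, and the 3 besides the real one gave 0.

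Y-linked RNA was lower and Xist higher in pulldown than in whole-cell libraries. The mean log2 change of the 4 Y-linked genes minus that of their X-linked homologs, over both mimics, was -1.63 (SE 0.05 over 4 gene pairs), which restates the pattern. Against 100 genes matched to each Y-linked gene on transcript length and abundance in whole-cell RNA, the mean difference was -1.68 (SE 0.15 over 4 genes), which argues against capture or loss by length or abundance as the whole cause. Capture by sequence was not tested. A candidate explanation is that pulldown and whole-cell libraries came from cultures with different shares of male and female cells. It stays open, since the homologs, which female cells express from both X chromosomes, differed from matched genes by 0.05 (SE 0.12 over 4 genes), which decides nothing. If this explanation holds, differences between pulldown and whole-cell RNA may include differences between cultures, for genes on other chromosomes too. The same goes for pulldown enrichment, where such differences do not cancel between the mimics. No biological explanation was tested.

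Changes under miR-27a in pulldown RNA followed those in whole-cell RNA. Capture of transcripts with miR-27a seed sites would place the seed 7mer among the most enriched, and its rank by t from the most enriched was 154 among it and 200 control 7mers, which argues against such capture as the source of the pattern. Background capture, so that pulldown RNA mirrors the RNA of the cells, stays open as a candidate explanation. Over genes that changed in whole-cell RNA, the slope of the pulldown change was 0.956 for 1152 genes with a miR-27a site and 0.905 for 2031 without, a difference of 0.051 (SE 0.024 over genes). Capture of a few transcripts through other kinds of pairing was not tested.

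Genes with GGTTGTG in the 3′ UTR were higher under miR-27a than under control mimic. Base composition is argued against by the other 34 7mers of the same composition, whose median t was 1.13 and highest 3.56 against 12.82. For release of transcripts from the cells' own miRNAs, the sites of 8 brain miRNAs had a median t of 0.71 and a highest t of 2.55. This cannot decide the question, since the activity of these miRNAs in the cells was not measured. A candidate explanation is that the control mimic represses its own seed sites, since genes with the site followed by A changed by 0.061 ± 0.012 (SE over genes) more than genes with the site followed by another base. No test over libraries, such as camera or fry, was run for these sites. The rises of Ccnb1 and Sae1, which carry GGTTGTGA, may then in part be an effect of the control mimic, whose sequence is not given in the sources used here. Of 1668 genes higher in whole-cell RNA with a 3′ UTR, 29.1% carried such a site or its 7mers, against 17.6% of the rest, so this leaves most of the rises open.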

How the results depend on the processing

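The alternatives with the deposited log2 values, limma voom on recovered reads and library totals were chosen after seeing the data, and the others before. Negative binomial count models, named as alternatives before the data were examined, were not run. No named gene with a call changed direction under the alternatives run. Counts stayed within 1.5 times the reported ones in 17 of 18 alternatives for whole-cell RNA, 10 of 18 for pulldown RNA and 12 of 23 for pulldown enrichment. They did so in 14 of 24 for the overlap of genes higher in pulldown and lower in whole-cell RNA, and 24 of 24 for pulldown against whole-cell RNA under each mimic (7766 to 9228 and 7519 to 10930 genes with all libraries). The cause was not tested for the exceptions below. Leaving out a library leaves fewer samples, which can lower a count but gives no account of the counts that rose.

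With all 12 libraries in 1 fit, 1415 genes changed in whole-cell RNA, 3051 in pulldown RNA and 3 in the overlap. Array weights gave 5102 genes in pulldown RNA, 1735 in pulldown enrichment and 28 in the overlap, and these fits did not reach their convergence tolerance. The replicate block gave 2743 in pulldown RNA and 11 in the overlap, and among the 23 lists fixed before the data were examined it changed the call in pulldown RNA of abundant small non-coding RNAs alone. No filter gave 73 in pulldown enrichment and 3 in the overlap.

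Leaving out 1 library gave 2379 to 3294 genes in whole-cell RNA, 969 to 2691 in pulldown RNA, 43 to 473 in pulldown enrichment, 2 to 16 in the overlap, 7777 to 9147 for pulldown against whole-cell RNA under control mimic and 7429 to 8441 under miR-27a. Pulldown RNA gave 1002, 1180 and 969 without pulldown control replicates 1, 2 and 3, and 2691 and 1029 without pulldown miR-27a replicates 2 and 3. Pulldown enrichment gave 54 and 53 without whole-cell control replicates 1 and 3, 57, 66 and 43 without whole-cell miR-27a replicates 1, 2 and 3, 90 and 49 without pulldown control replicates 1 and 3, and 359 and 473 without pulldown miR-27a replicates 1 and 2. The overlap gave 2 and 3 without whole-cell miR-27a replicates 1 and 3, 3 without pulldown control replicate 1 or 3, and 16 and 3 without pulldown miR-27a replicates 1 and 3.

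Library totals made 60.2% of the genes that differed between pulldown and whole-cell RNA under miR-27a higher, against 48.7%, and 60.3% under control mimic, against 51.1%. They turned the balance in pulldown RNA to 925 higher and 823 lower and the median of ribosomal protein genes under miR-27a from -0.10 to 0.01. Median-of-ratios scaling turned the balance in whole-cell RNA to 1654 higher and 1689 lower, and under control mimic to 4232 and 4348, as the filter of at least 5 CPM did to 3793 and 3973. Median-of-ratios scaling made 42.4% higher in pulldown enrichment, against 31.5%. Median differences of genes with miR-27a sites kept their sign and, by camera at the preset correlation, their side of the threshold, from -0.117 to -0.0454 in whole-cell RNA, -0.118 to -0.0423 in pulldown RNA and 0.00407 to 0.00849 in pulldown enrichment. In pulldown RNA none passed with an estimated correlation (p = 0.0531 for the 8mer and 0.155 to 0.206 for the others). By fry, which allows for correlation, the 8mer passed there (p = 0.0104) and sites of any kind did not (p = 0.0657, and 0.0515 to 0.342 over alternatives). Calls of named genes changed under at least 1 alternative for 29 of 106 in whole-cell RNA, 42 of 105 in pulldown RNA and 54 of 106 in pulldown enrichment, and for 0 of 6 under each mimic for pulldown against whole-cell RNA. Replicate numbers of pulldown and whole-cell libraries under miR-27a correlated at 0.015, 0.161 and 0.132, not all above 0.1, and were not taken as pairs. Small changes are limited by the 3 libraries per group, and 24% of the smallest simulated changes were recovered in pulldown enrichment, with a spread pooled over the groups.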

Other observations

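The test of direct repression was planned, and the list of contractile genes was chosen after the results were seen. In whole-cell RNA the miR-27a seed 7mer ACTGTGA had rank 1 by t from the lowest among it and 200 control 7mers, and the 7 of 12 smooth-muscle contractile genes that fell, a list that holds genes already seen to fall, included Myl9, Cnn1 and Tagln, which carry no site. Direct repression by the mimic may account for part of the falls, since 32.3% of genes with the 8mer fell against 9.1% of genes without a site, and 785 genes without a site fell as well. Of the latter the source was not tested.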
